A study of Mus musculus with 17 samples.

How the data were processed

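RNA was taken from mouse brain, white and grey matter of the territory of the middle cerebral artery. It was measured on 17 oligonucleotide arrays of 1 design with 12488 probe sets. Probe names and the platform annotation are those of an Affymetrix mouse array. The 12 pooled arrays each carried RNA pooled from 6 brains, 3 arrays in each of 4 groups. The groups were control pools given saline, drug control pools given AEOL 10150, ischemic pools, and ischemic pools given AEOL 10150 (treated ischemic pools). The other 5 arrays each carried 1 brain given AEOL 10150 and ischemia. AEOL 10150 is a catalytic antioxidant. Control tissue was collected 6 h after the injection. Ischemic tissue was collected after 1 h of ischemia and 6 h of reperfusion. The labels do not say whether the untreated ischemic mice were given saline, and they give no dose.

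The deposited values are intensities, 1 per probe set and array, on a linear scale. The software and the scaling the authors used are not given in the sources used here. Between 15.2% and 19.3% of the values of an array were below 0, a feature of intensities from which a mismatch or background signal has been subtracted. On 10 arrays the mean of the values between the 2nd and 98th percentiles was 2500, so these had been scaled to a common level. On 7 arrays, namely treated ischemic pools 2 and 3 and all single brains, that mean lay between 129 and 210 and differed from array to array. Arrays carry no read depth; their number, 3 per pooled group, limits the precision.

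Groups of the pools were taken from the sample titles. The single brains have titles like those of the treated ischemic pools and were set apart by their descriptions, which give 1 brain each; the brain numbered 11 in its description is numbered 4 in its title. For 2 pooled arrays the description lacks the treatment that the title names: drug control pool 1 is described as given saline, and treated ischemic pool 1 is described with no drug. Treated ischemic pool 2 is described as the first replicate of its group. The comparisons were therefore run again with groups from the descriptions, and again without the 2 arrays.

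Each array was multiplied by a factor that brought its trimmed mean to 2500. Values under the 25th percentile of the scaled pooled arrays, an intensity of 109.5, were set to that floor, and log2 was taken, so the floor was 6.77 on the log2 scale. A fold against a group with every array at the floor is a lower bound. Such a group has an SD of 0, which lowers the standard error and the p value. The 66 array control probe sets were left out of tests. Probe sets above the floor on at least 3 arrays of a fit were tested, 10259 in the pooled arrays and 10185 in the fit of ischemic pools and single brains. Of the probe sets, 10855 paired with 1 gene symbol, 396 with several and 1237 with none; symbols are those of the platform annotation, of which 10839 were updated or kept through its Entrez gene numbers, and no genome positions were used.

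Linear models were fitted with limma 3.58.1 in R 4.3.3. The 12 pooled arrays were fitted together and shared 1 estimate of the spread, with 8 residual and 2.23 prior degrees of freedom. Benjamini-Hochberg adjustment ran over probe sets within each comparison, with a threshold of 0.05. The 5 comparisons of pools came from this fit: ischemia without the drug, ischemia with the drug, the drug after ischemia, the drug without ischemia, and the difference between the 2 ischemia responses. The single brains were compared with the ischemic pools in a separate fit. All p values are two-sided. Those of the 12 pooled arrays concern the spread between pools; those of the single brains rest on a spread taken over pools and single brains together. With 3 arrays against 3, an exact permutation test cannot go below p = 0.1, so no such test was made per gene.

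The named genes followed a fixed rule. In each comparison of pools they were the 15 largest rises and 10 largest falls past the threshold, with 1 symbol, both group means above the floor and no overlap between the 3 values of each group. Where fewer than 5 passed, the 5 smallest p values in each direction were taken. Up to 4 further members of each gene list were added. Other genes past the threshold are named outside this rule and were chosen after their values were seen.

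There were 27 gene lists covering stress and inflammatory pathways, cell types, brain regions, metabolism, sex-linked transcripts and time of day. They were tested with limma's camera at a preset correlation of 0.01, with the brightest probe set of each of 7280 genes. The adjustment ran over the lists of a comparison. Camera with an estimated correlation and fry were run as alternatives. The groups, lists, named-gene rule, designs and most alternatives were chosen before the data were examined.

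The pooled groups share the replicate numbers 1 to 3, and the labels do not say what a number marks. Among control, drug control and ischemic pools, arrays with the same number deviated together from their group means in all 9 pairs, with correlations over probe sets from 0.33 to 0.57. Pairs with different numbers gave -0.51 to 0.13. Deviations from a group mean cancel out within the group, so high same-number values push these down, and they are no separate evidence. From the same-number pairs, the numbers were read as pairing these 3 groups. In pairs with the treated ischemic pools the correlations differed by number. They were 0.059 to 0.21 for treated pool 1, 0.19 to 0.40 for treated pool 2 and -0.34 to -0.11 for treated pool 3. The numbers were therefore not read as pairing that group as a whole. The fit with the replicate number as a block was run as an alternative.

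The alternatives were values as deposited, quantile normalization, a floor at the 40th percentile, no filter, a filter asking for all arrays, array weights, a trended and robust prior, fits of only the 2 groups compared, a fit of all 17 arrays, the replicate block, other readings of the labels, and each array left out in turn. A term for the scale set, meaning whether an array had been deposited on the common level, was added after seeing the data. The pipeline was tested on simulated data with changes put into the pooled design: 13.4% of 2-fold changes, 68.7% of 4-fold changes and 74.2% of 8-fold changes were recovered, with 1 unchanged probe set among 105 calls.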

Results

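The data cover 17 arrays of mouse brain from the territory of the middle cerebral artery. There were 3 pools of 6 brains in each of the control, drug control, ischemic and treated ischemic groups, and 5 single brains that had been given AEOL 10150 and ischemia. After scaling, between 24.3% and 26.5% of the values of an array lay at or below the floor. The 3'/5' signal ratio of the actin control, a measure of RNA integrity, ran from 1.15 to 1.19 in replicate 3 of the control, drug control and ischemic pools. It ran from 1.65 to 1.97 in replicate 1 and from 1.33 to 2.14 in replicate 2 of the same groups. The range was 1.29 to 1.68 in the treated ischemic pools and 1.38 to 1.60 in the single brains. By group, the median was 1.97 in drug control pools (1.15 to 2.14), 1.33 in control, 1.53 in ischemic and 1.34 in treated ischemic pools. Comparisons with the drug control pools thus also differ in this ratio. The ratio of the Gapdh control ordered the replicates of the same 3 groups otherwise, with 0.970 to 1.06 in replicate 1, 1.16 to 1.55 in replicate 2 and 1.04 to 1.09 in replicate 3.

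The principal components of the pooled arrays separated replicate numbers more than treatments. The first component held 30.6% of the variance; replicate number accounted for 58.4% of it and group for 5.74%. The second held 19.5%, with 68.7% for replicate number and 11.0% for group.

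**Figure D1:**
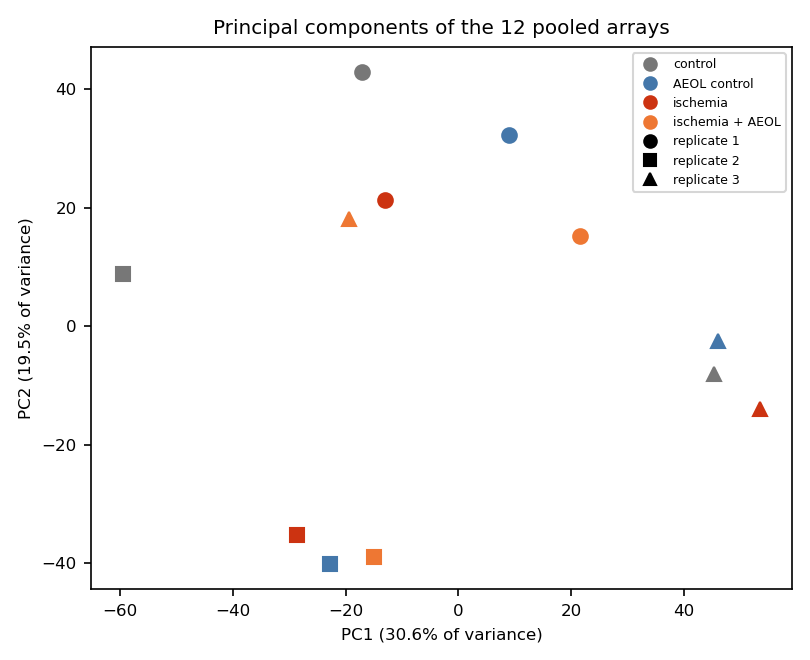
Scores of the 12 pooled arrays on the first component (30.6% of the variance, horizontal) and the second (19.5%, vertical), in arbitrary units; colour gives the group and the symbol gives the replicate number. The 3 pools numbered 3 of the control, drug control and ischemic groups lie together at the right, away from treated ischemic pool 3.

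The first comparison asked how brain tissue responded to ischemia and reperfusion without the drug. The largest rises were in the inducible heat shock proteins Hspa1b (probe set 100946_at; log2 16.07 ± 0.24 in ischemic and 11.43 ± 0.97 in control pools, SD, n = 3 each; log2 difference 4.64, SE 0.51) and Hspa1a (93875_at; 19.6-fold, log2 difference 4.30, SE 0.43). The stress and activity-induced transcription factors Atf3 (12.0-fold), Fos (10.3-fold), Fosb (4.52-fold), Egr1 (3.70-fold) and Nr4a1 (3.46-fold) rose as well, with standard errors of 0.20 to 0.39 on the log2 scale. So did Gadd45b (8.05-fold) and Gadd45g (4.01-fold), which are induced by growth arrest and DNA damage. The chemokine Ccl3 rose 4.47-fold (SE 0.30 log2), and the neutrophil calcium-binding protein S100a8 rose 4.45-fold (SE 0.32 log2) from a level above the floor in 2 of 3 control pools. Other rises were those of the hyaluronan-binding protein Tnfaip6 (4.76-fold), the cochaperones Dnajb1 (4.60-fold) and Bag3 (3.69-fold), and Socs3 (3.33-fold), a feedback inhibitor of cytokine signalling.

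In all, 22 probe sets rose and 0 fell in limma, with 423 at an unadjusted p under 0.05 where chance gives 513. Adjusted p values of the 22 ran from 0.000266 to 0.0366. Outside the rule, the 7 others were the retinaldehyde dehydrogenase Aldh1a3, Gfpt2, Nfkbiz, Rrad, Procr, Ifi207 and 1 probe set shared by several genes (160469_at, 4.94-fold). Aldh1a3 was at the floor in all control pools and at least 3.31-fold higher in ischemic pools. Gfpt2, an enzyme of the hexosamine pathway, rose 3.19-fold, and Nfkbiz, a nuclear regulator of NF-kB, rose 3.21-fold. Rrad rose 2.80-fold and the endothelial protein C receptor Procr 2.61-fold. Ifi207 rose 2.18-fold from a level above the floor in 1 control pool, so that fold depends on the floor.

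**Figure D2:**
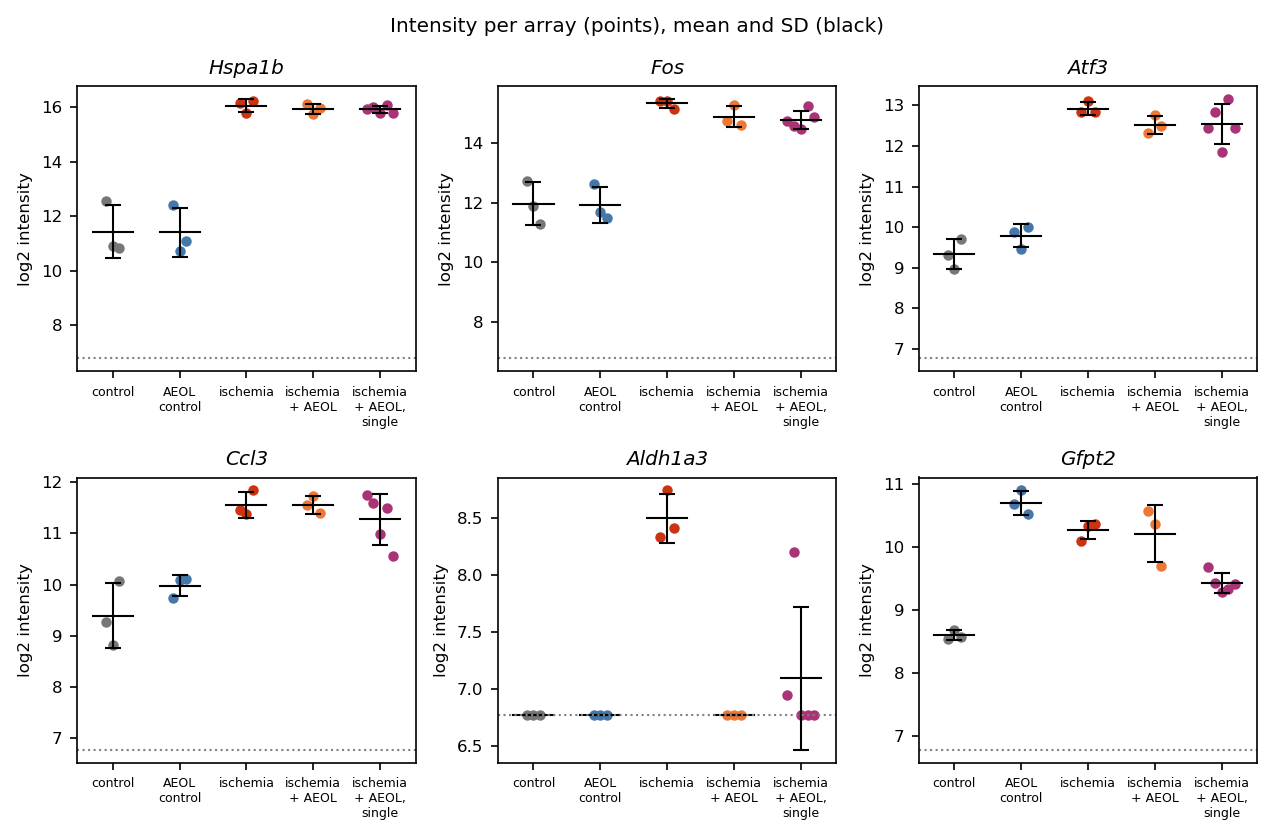
log2 intensity (vertical) of 6 genes in each array (points) by group, with the mean and SD in black and the floor as a dotted line. All ischemic arrays lie above all control arrays for Hspa1b, Fos, Atf3 and Ccl3; Aldh1a3 is above the floor in the 3 untreated ischemic pools and in 2 of 5 single brains; Gfpt2 is lowest in control pools, with a mean of 8.59.

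Among the lists, the immediate early genes were higher in 29 of 29 members, with a median log2 difference of 1.15. Of them 5 passed over all probe sets and 23 adjusted over the list alone (camera adjusted p = 2.01e-39). The heat shock list rose with a median of 0.34; 4 of 23 members passed over all probe sets and 7 adjusted over the list alone (adjusted p = 4.85e-12). The cytokine and chemokine list rose with a median of 0.85 over 20 genes, of which 1 passed over all and 7 adjusted over the list alone (adjusted p = 1.04e-09). Its members Ccl2 (log2 difference 3.38, SE 0.59), Cxcl1 (3.83, SE 0.68) and Cxcl2 (2.71, SE 0.52, control pools at the floor) had adjusted p values of 0.0608, 0.0681 and 0.113 over all probe sets and of 0.00136, 0.00136 and 0.00199 adjusted over the list alone. The list of NF-kB targets and leukocyte adhesion rose with a median of 0.31 over 31 genes, 2 over all and 7 adjusted over the list alone (adjusted p = 1.03e-07). In it, the adhesion molecule Icam1 had a log2 difference of 2.42 (SE 0.44) and an adjusted p of 0.0725.

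The unfolded protein response rose as a list (20 genes, median 0.31, adjusted p = 0.00142), although 0 members passed in limma over all probe sets or adjusted over the list alone. Its chaperone Hspa5 had a log2 difference of 0.69 (SE 0.20). Cell death and DNA damage rose (30 genes, median 0.27, adjusted p = 0.00314), with 2 members passing either way, Gadd45b and Gadd45g. Endothelium and mural cells rose (33 genes, median 0.20, adjusted p = 0.00211), with Procr alone passing either way. The calls for these 7 lists held with an estimated correlation, with adjusted p values from 0.00011 to 0.0493. Neutrophil genes (16 genes, median 0.59) and the interferon response (26 genes, median 0.36) passed at the preset correlation with adjusted p values of 5.81e-05 and 0.00117. These calls were lost with adjusted p = 0.0936 and adjusted p = 0.195 with an estimated correlation; S100a8 was the neutrophil gene past the threshold and 0 interferon genes passed either way.

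Genes of striatal neurons fell as a list. All 8 were lower, with a median of -0.45 (adjusted p = 2.17e-05; adjusted p = 0.00758 with an estimated correlation). None passed over all probe sets; 2 fell adjusted over the list alone, the dopamine receptor Drd2 (log2 difference -0.83, SE 0.25) and Rasgrp2 (-1.13, SE 0.33).

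The other 17 lists did not pass. Adjusted p values were 0.0514 for oligodendrocytes (median 0.15) and for red blood cells (0.27), 0.054 for microglia (0.21), 0.0608 for cortical and hippocampal neurons (-0.16), 0.0689 for sterol synthesis (0.13), and 0.139 for growth factors and neuropeptides (0.16). They were 0.226 for lymphocytes (0.38), 0.259 for neurons (-0.067), 0.389 for NADPH oxidase and nitric oxide synthases (0.049), 0.393 for thalamus and hypothalamus (-0.088), and 0.58 for circadian and glucocorticoid response (0.053). For oxidative phosphorylation (-0.025), choroid plexus and meninges (0.085), antioxidant and oxidative stress genes (-0.0026), astrocytes (0.052), hypoxia and glycolysis (0.019) and sex-linked transcripts (0.21) they lay between 0.584 and 0.894. The median was above 0 and the mean below 0 for the NADPH oxidase list, the sex-linked list and astrocytes; the reverse held for the antioxidant list and oxidative phosphorylation. The test pointed down for the NADPH oxidase list, the sex-linked list and oxidative phosphorylation. In the antioxidant list, the heme oxygenase Hmox1 had a log2 difference of 0.97 (SE 0.39; adjusted p = 0.653 over the list alone).

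With replicate number as a block, 35 probe sets passed for ischemia without the drug, 34 up and 1 down (Dazl, log2 difference -1.58), and 20 of the 22 were shared. S100a8 (adjusted p = 0.0606) and Tnfaip6 (0.0569) were lost, and Cxcl2, Icam1, Ier2, Jun, Junb and Ptgs2 were among those added. The SE went from 0.321 to 0.343 for S100a8 and from 0.356 to 0.354 for Tnfaip6. In the blocked fit 16 lists passed in place of 10; the added ones were oligodendrocytes (0.0256), red blood cells (0.0256), microglia (0.0348), cortical and hippocampal neurons, lower (0.035), sterol synthesis (0.041) and growth factors (0.049). With an estimated correlation in the unblocked fit these 6 had adjusted p values from 0.133 to 0.195. The unblocked count depended on single arrays: it was 9 and 7 without control pools 1 and 2, and 1, 5 and 1 without ischemic pools 1, 2 and 3.

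**Figure D3:**
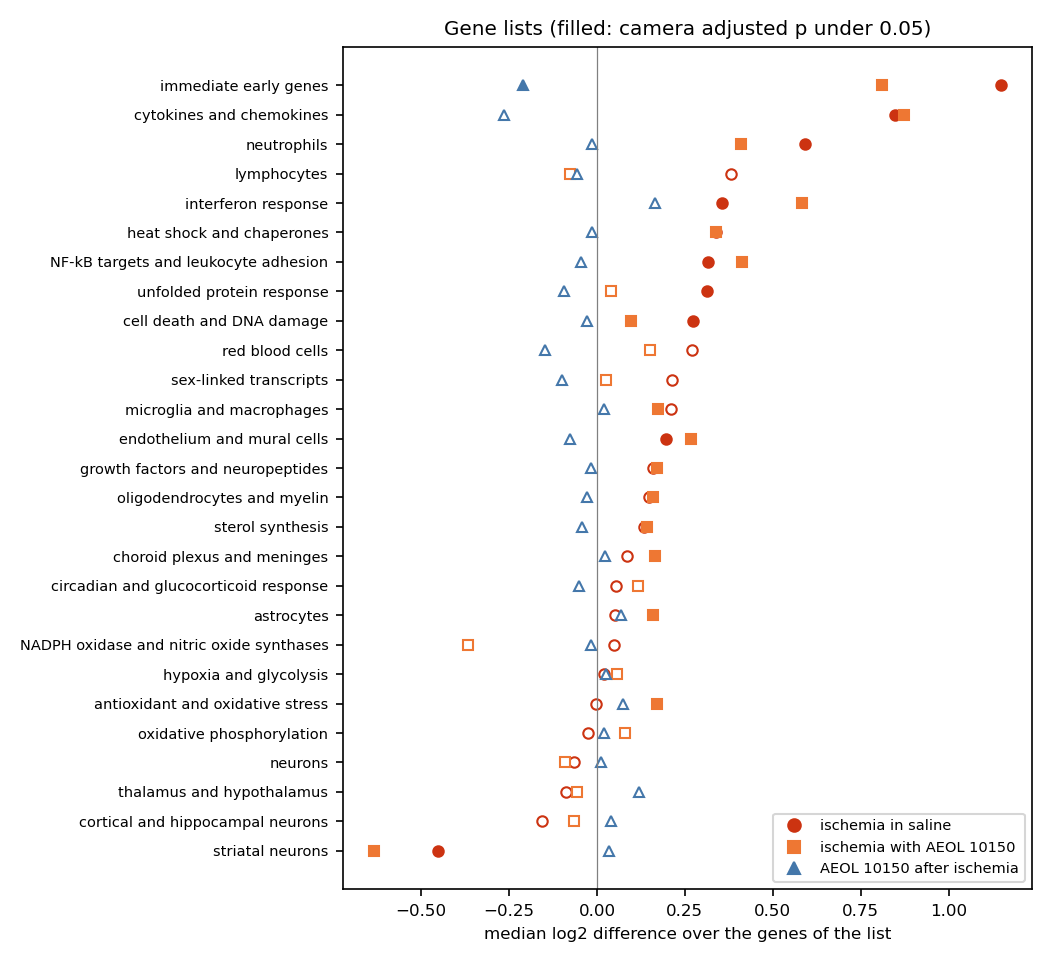
Median log2 difference over the genes of each of 27 lists (horizontal) for ischemia without the drug (circles), ischemia with the drug (squares) and the drug after ischemia (triangles); filled symbols passed camera at the preset correlation. Immediate early genes had the highest median without the drug (1.15) and striatal neurons the lowest (-0.45); arrays were brought to a common level, and with values as deposited the squares and triangles shift down, by an amount that differs between lists, and the median of all genes lies at -2.48 and -2.51.

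The second comparison set treated ischemic pools against drug control pools. Hspa1b (23.3-fold, SE 0.51 log2), Hspa1a (17.3-fold, SE 0.43), Fos (7.73-fold, SE 0.39) and Atf3 (6.67-fold, SE 0.24) rose most. Gadd45g (3.92-fold), Dnajb1 (3.87-fold), Nr4a1 (3.77-fold), Egr1 (3.67-fold) and Bag3 (3.26-fold) also rose, with adjusted p values of the 9 from 0.00365 to 0.0385. No probe set fell in limma, with 353 at an unadjusted p under 0.05. All 9 were among the 22 of the first comparison, which shares no array with this one but the estimate of spread per probe set. Of the 22, 20 were higher with the drug and 19 of these had an unadjusted p under 0.05.

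Immediate early genes (median 0.81; 4 of 29 over all, 13 adjusted over the list alone; adjusted p = 7.78e-27) and heat shock genes (0.34; 4 of 23, 7 adjusted over the list alone; 4.42e-17) rose. Cytokines and chemokines (0.87; 0 of 20, 6 adjusted over the list alone; 1.1e-10) and NF-kB targets (0.41; 0 of 31, 5 adjusted over the list alone; 3.8e-07) rose as lists. Endothelium and mural cells (0.27; 0 of 33, 1 adjusted over the list alone, Procr; 0.00105) and growth factors and neuropeptides (0.17; 0 of 32 either way; 0.00637) did so too. Striatal neuron genes were lower in 8 of 8, with a median of -0.63 (4 fell adjusted over the list alone; 1.19e-07), Drd2 by a log2 difference of -0.93 (SE 0.25). These 7 calls held with an estimated correlation, at adjusted p values from 0.000238 to 0.0352. At the preset correlation 9 further lists passed with higher values: interferon response (median 0.58), antioxidant and oxidative stress genes (0.17), cell death, astrocytes, oligodendrocytes, microglia, neutrophils, choroid plexus, and sterol synthesis. Their adjusted p values were 0.0653 to 0.204 with an estimated correlation, so these calls were lost. With values as deposited, which shifted the median of all genes by -2.48 because 2 treated pools were on another scale, the higher lists lay below 0, for instance -1.70 for immediate early genes and -2.24 for heat shock genes, but above that shift.

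The treated ischemic pools were deposited on different scales, with pool 1 alone on the common scale. With the scale set as a block that pool, whose description names no drug, stands alone for its group. Counts of passing in that fit would rest on 1 array and are not given. All 9 probe sets that passed were higher in that pool than in the drug control pools, by 1.67 to 4.72 log2. List medians in that fit were 0.82 for immediate early genes, 0.33 for heat shock genes and 0.94 for cytokines and chemokines. They were 0.43 for NF-kB targets, -0.94 for striatal neurons and -0.15 for neurons. Sterol synthesis had 0.18, microglia 0.14, oligodendrocytes 0.19, growth factors 0.18, astrocytes 0.11, antioxidant genes 0.0092 and choroid plexus 0.084. With replicate number as a block 12 passed in limma and 8 of the 9 were shared, although the numbers were not read as pairing the treated pools. Bag3 was lost (adjusted p = 0.0634), while its SE was 0.244 without and 0.241 with the block. Without drug control pools 2 and 3 the unblocked count was 5 and 1, and without any treated ischemic pool it was 1.

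**Figure D4:**
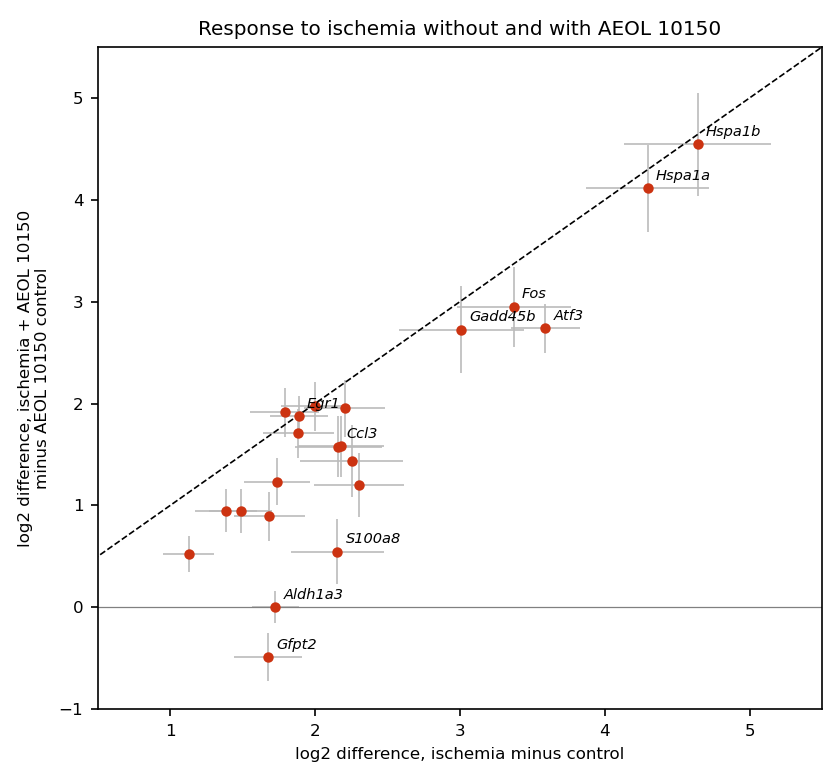
log2 difference between ischemic and control pools (horizontal) and between treated ischemic and drug control pools (vertical) for the 22 probe sets that rose without the drug; bars are standard errors and the dashed line marks equal differences. Points lie under the line for 21 of the 22 (medians 2.08 and 1.58); they were chosen on the horizontal value, and this alone moves points under the line.

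The third comparison, treated against untreated ischemic pools, asked what the drug did in ischemic brain. Aldh1a3 was at the floor in all 3 treated pools and at least 3.31-fold lower than in untreated ischemic pools (adjusted p = 0.00641). It was also at the floor in all control and drug control pools, so its SD was 0 in these groups. The floor thus lowers its SE and p value. Among the 5 single treated brains it was above the floor in 2. No other probe set passed in limma, 0 rose, and 151 had an unadjusted p under 0.05. The cell cycle gene Ccna2 had a log2 difference of -2.11 (SE 0.32, adjusted p = 0.297), with treated pools at the floor. The other genes with the smallest p values were Cyct, Sp100, Slc35g3, Mrps5 and Cd37 on the higher side (log2 differences 0.80 to 2.97) and Crygd, Nabp1 and Abcd2 on the lower (-2.16 to -0.86), all with an adjusted p of 1.

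Of the inflammatory genes, Cxcl2 had a log2 difference of -1.29 (SE 0.52), Il6 of -1.18 (SE 0.52) and Cxcl1 of -0.77 (SE 0.68); each had an adjusted p of 1, and of 0.462, 0.462 and 0.913 adjusted over the list alone. For Cxcl2 and Il6 1 of the 3 treated pools was at the floor, so these 2 differences depend on the floor. Cytokines and chemokines were lower in 12 of 20 (median -0.26, adjusted p = 0.218) and NF-kB targets in 17 of 31 (median -0.044, adjusted p = 0.847). The interferon response was higher in 18 of 26 (median 0.16, adjusted p = 0.102; 0.91 with an estimated correlation). With the replicate block, whose numbers were not read as pairing the treated pools, the camera adjusted p was 0.0344. Immediate early genes fell as a list. The genes were lower in 26 of 29, with a median of -0.21 (adjusted p = 0.000389), and 0 passed in limma over all probe sets or adjusted over the list alone; Atf3 had -0.40 (SE 0.24) and Homer1 -0.53 (SE 0.30). The call was lost with an estimated correlation (adjusted p = 0.202), and fry gave 0.974.

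With the scale set as a block, treated ischemic pool 1 alone stood for the treated group. The immediate early list then had a median of -0.16, which is the value of that pool minus the untreated ischemic pools. The log2 difference of Aldh1a3 was -1.73 in both fits. With groups from the descriptions, or without any 1 of the 6 arrays, 0 probe sets passed in limma, and without ischemic pool 3 the count of lists was 0.

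Of the 22 probe sets that rose with ischemia, 19 (86.4%) had lower means in treated than in untreated ischemic pools, with a median log2 difference of -0.23. The untreated ischemic pools enter both sides of this count. In 100 simulations with no drug effect the share had a median of 69.9% (95% between 54.2% and 84.3%) and the median difference was -0.18 (-0.29 to -0.041). The simulated noise was independent between probe sets and arrays, without correlation between genes, pairing by replicate number or a scale set. The share was as high in 1 simulation and the median as low in 23. Correlation between genes can widen the simulated range, so these ranks do not decide the question. The share was 75.0% with the scale set as a block, where treated ischemic pool 1 alone stands for its group. It was 71.4% with groups from the descriptions and 100% without the 2 arrays with unlike labels. No simulations were made for these settings. In treated ischemic pool 1 alone, on the common scale, 16 of the 22 were lower. Of 282 probe sets that were higher in the single treated brains than in drug control pools, 104 (36.9%) were lower in treated than in untreated pools. Choice by high values in treated brains favours the treated pools here, and no value under no drug effect was computed.

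The fourth comparison gave the drug to mice without ischemia. Gfpt2 rose 4.31-fold (log2 10.70 ± 0.19 in drug control and 8.59 ± 0.08 in control pools, SD, n = 3 each). It was the 1 probe set that passed (limma adjusted p = 0.036); 0 fell, and 264 had an unadjusted p under 0.05. The estrogen receptor Esr1 had a log2 difference of 1.28 (SE 0.19, adjusted p = 0.297) from controls at the floor, and the glutathione transferase Gstm5 one of -2.93 (SE 0.58, adjusted p = 1) to drug controls at the floor. Krt33b, Rusc1 and Gabra6 on the higher side (0.87 to 1.29) and Lcp1, Neurog2, Spa17 and B3gnt2 on the lower (-1.84 to -0.73) had an adjusted p of 1. Of the 27 lists 0 passed camera, 2 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0929. With the replicate block, which by design leaves the log2 difference of 2.11 as it is, 0 probe sets passed in limma. Gfpt2 was lost (adjusted p = 0.0952), although its SE was 0.23 without and 0.21 with the block. The block leaves fewer residual degrees of freedom, so this loss does not show a weaker difference. With groups from the descriptions 0 passed as well. The count was also 0 without control pool 1 or 2 or any drug control pool, and 2 without control pool 3.

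The response to ischemia was then compared between mice with and without the drug. In limma 0 probe sets differed, 213 had an unadjusted p under 0.05, and the smallest adjusted p was 0.155, that of Aldh1a3 (log2 difference of differences -1.73, SE 0.23), which was at the floor in all pools but the untreated ischemic ones, so that the floor sets this value. Gfpt2 followed with -2.16 (SE 0.33, adjusted p = 0.307). Ccna2, Esr1 and Hgf on the lower side (-2.17 to -1.28) and Cyp1b1, Zcchc3, Acan, Lama4 and Tbp on the higher (1.1 to 3.17) had an adjusted p of 1.00. Ccna2 and Hgf were at the floor in all treated ischemic pools, and Esr1 and Cyp1b1 were above it in 1 of 3 untreated ischemic pools. The differences of these genes therefore depend on the floor. Immediate early genes were the 1 list that differed. Their response was smaller with the drug in 27 of 29, with a median of -0.37 (camera adjusted p = 0.00239, and 0.335 with an estimated correlation). With the scale set as a block, which leaves treated ischemic pool 1 alone in its group, the median was -0.32. With the replicate block, whose numbers were not read as pairing the treated ischemic pools, astrocytes passed as well (median 0.13, camera adjusted p = 0.0459). Their adjusted p was 0.068 without the block and 0.821 with an estimated correlation. Without control pool 3 the count of lists was 0. Part of the difference in immediate early genes came from mice without ischemia, where the list was higher with the drug in 19 of 29 (median 0.13, camera adjusted p = 0.531).

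The 5 single treated brains were set against the untreated ischemic pools. The receptor Gpr3 rose 6.27-fold and the ciliary gene Bbs9 rose 4.27-fold, each above the floor in 1 of the 3 pools, so these folds depend on the floor. Fntb, Inhbb, Fbln1, Mre11a and the unnamed probe set 101611_at were at the floor in all pools and at least 5.43-, 3.19-, 2.97-, 2.46- and 3.72-fold higher. Tbx2 was at the floor in all single brains and at least 6.94-fold lower. Clpx (log2 difference -1.39), the caspase inhibitor Xiap (-1.58) and the unnamed probe set 96135_at (-1.07) fell; Clpx and Xiap were above the floor in 2 of the 5 single brains, so their differences depend on the floor. That made 7 up and 4 down in limma, with 2178 at an unadjusted p under 0.05 where chance gives 509. Without ischemic pools 1 and 2 the count was 41 and 20, and without single brain 13 it was 4. All single brains were off the common scale and all untreated ischemic pools on it, so the scale set and the group cannot be told apart within these 2 groups.

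Against the pools given the same treatment, single brains were at least 6.76-fold higher in Gpr3, 5.39-fold in Bbs9, 3.72-fold in 101611_at and 2.97-fold in Fbln1, all of which were at the floor in the pools. No probe set was lower, and 1130 had an unadjusted p under 0.05. With the floor at the 40th percentile 0 passed in limma, and with the scale set as a block 8 did; without treated ischemic pools 1 and 3 the count was 8 and 98, and without single brain 11 or 12 it was 9. In both comparisons of single brains 0 lists passed camera, with 4 at an unadjusted p under 0.05 in each. These calls of the 2 comparisons were named after their values were seen.

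The median SD of a probe set was 0.238 log2 over the 5 single brains and 0.342 over the treated ischemic pools, a ratio of 1.44. It was 0.401 in control, 0.348 in drug control and 0.389 in ischemic pools. With fewer arrays in a group the median SD lies lower by construction, and no test was made.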

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

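Of the tests here, those of the single treated brains, of low intensities, of a distant single brain, of both explanations for the striatal genes and of the scale set term were chosen after the results were seen.

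Immediate early genes were picked out because their response to ischemia differed between mice with and without the drug by the list test at the preset correlation, with a median difference of differences of -0.37 (adjusted p = 0.00239; 0.335 with an estimated correlation, which does not pass). The 5' probe set of the array control for 18S ribosomal RNA, which no comparison used, read 31299.1 on ischemic pool 2 after scaling, against at most 842 in the control pools and 8007 on treated ischemic pool 2. Of 45 values over the 5 single brains, 41 of genes above the floor in at least 4 of them and 4 of array measures, 2 had a brain far from the others, where chance gives about 1 in 20. The choroid plexus transcript Ttr stood at the floor of 6.77 log2 in single brain 11 and at 12.82 to 13.95 in the other 4; Drd2 stood at 10.95 in single brain 13 and at 10.24 to 10.43 in the others.

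Immediate early genes were lower in treated than in untreated ischemic pools, with a list median of -0.21. Drug control pools had a list median of 0.13 over control pools, and this part of the difference between the responses was not followed up. The treated pool deposited on the common scale had -0.16 (95% over genes -0.36 to 0.020) and the other 2 treated pools together -0.26; the description of the pool on the common scale names no drug, so with 1 pool on that scale, of uncertain treatment, the 2 deposited scales and the treatment cannot be told apart. Leaving out 1 untreated ischemic pool gave at most -0.20, with an upper bound of -0.091 against a limit set at -0.1, which leaves 1 high pool open. The single treated brains had -0.24 (-0.37 to -0.11) against the same 3 untreated ischemic pools and were all deposited off the common scale, so a lower response in treated brains stays open beside the scale and 1 high pool. The labels do not say whether these brains were part of a treated pool, and they correlated with treated pool 3 at 0.964 to 0.973, as among themselves (0.961 to 0.972).

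Genes of striatal neurons were lower after ischemia in 8 of 8, with medians of -0.45 without and -0.63 with the drug. Loss of neurons of every kind would lower neuron genes as far. The neuron list had a median of -0.067 (95% over genes -0.14 to -0.015) without and -0.091 (-0.21 to -0.013) with the drug, which argues against it in these pools. The ranges are over genes and do not hold the spread between pools. Less striatum in the dissected tissue would raise markers of neighbouring regions. Cortical and hippocampal genes had medians of -0.16 (-0.38 to 0.090) without and -0.065 (-0.42 to 0.077) with the drug. Thalamus and hypothalamus genes had -0.088 (-0.28 to 0.10) and -0.055 (-0.20 to 0.15). None of these medians lay above 0, but each range reaches above it, which leaves the explanation open. A response of striatal neurons to ischemia, from the tissue the labels name, also stays open and was not tested.

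Pools of 6 brains spread more than single brains, although pooling averages over animals. Low intensities may inflate a spread on the log2 scale, but among the brighter probe sets the ratio of median SDs, treated ischemic pools over single brains, was 1.61, which argues against them. Batches by replicate number could account for part in the other 3 groups of pools: there the ratio of root mean square SDs fell from 1.57 to 1.14 with the replicate number removed, between the limits set for either answer. The treated ischemic pools, whose numbers were not read as pairing with the others, had a ratio of 1.42. They were deposited on both scales, 1 pool on the common scale and 2 off it, while all 5 single brains were off it. A difference between the scale sets can therefore enter the spread of these pools. Without the pool on the common scale, as without any other 1 array of these 2 groups, the ratio of median SDs lay between 1.09 and 1.56. The other pools were all on the common scale. No biological explanation was tested.

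For ischemia without the drug 1 of the 10 splits of the 6 arrays, the real one, gave as many probe sets, 22 against at most 1 in the others and at most 0 in those that part as many pairs. For ischemia with the drug it was also 1 of 10, with 9 against at most 1. For the drug after ischemia 6 of 10 splits gave at least the real count of 1, with 4 the highest other. For the drug without ischemia 4 of 10 did, with 9 the highest other; that split and each other split that gave more than 0 kept pairs together, and those that part as many pairs as the real one gave 0. Splits of 3 arrays against 3 are too few for a share under 0.05. For the difference of the responses the real count was 0, which 100 of 100 drawn splits reach by necessity, so this count decides nothing; the highest other gave 26, which points to structure among the arrays. For the single brains against untreated pools 1 of 56 splits gave 11, with 3 the highest other, and against treated pools 1 of 56 gave 4, with 3 the highest other. In both, 1 of 56 is a share under 0.05, with no adjustment over comparisons. Against treated pools the margin was 4 against 3, and with the floor at the 40th percentile 0 probe sets passed. Single brains and pools also differed in spread, scale set and pooling, and the splits cannot tell these apart. A chance division is therefore not excluded.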

How the results depend on the processing

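The list tests other than those with an estimated correlation or fry, the term for the scale set, the share of raised probe sets under other settings of the labels and the spread ratios were tests chosen after the results were seen. Over the settings run, named genes kept their side of the threshold in 899 values, were weaker in 267, stronger in 7 and reversed in 5. Direction was compared only where the main fit passed, so a change of sign among values that passed in neither fit counts among those kept. Lists did so in 690, 34, 7 and 9. Counts and spread ratios within 1.5 times, and shares within 10 percentage points, made up 132 values that stayed the same. Others were lower in 58, higher in 40, moved in 7 and reversed in 1. The cause was not tested except where stated. The floor at the 10th percentile was not run, because that percentile was -139 and has no logarithm. The signal over background limits genes near the floor, where 24.3% to 26.5% of an array's values lie.

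Values as deposited shifted the median of all genes by -2.51 (drug after ischemia) and -2.48 (ischemia with the drug), since 2 treated pools were on another scale. They gave 0 probe sets for ischemia without the drug and 0 for the drug without ischemia. The control, drug control and ischemic pools were deposited at 2500, so scaling changed only their floor. The spread was shared with the treated ischemic pools, which lay on 2 scales in that fit, so these counts of 0 do not show a missing response. For the drug after ischemia 7132 passed and for ischemia with the drug 6935, all lower. Lists passing were 2 for the drug after ischemia, 1 for the drug without ischemia and 8 for ischemia with the drug. For ischemia with the drug, Gadd45g was reversed at -0.66, Dnajb1 at -0.68, Nr4a1 at -0.71, Egr1 at -0.75 and Bag3 at -0.92, all above the shift. List medians were reversed for immediate early genes (-1.70), heat shock (-2.24), cytokines (-0.18), NF-kB targets (-1.72), neutrophils (-1.86), interferon (-2.05), endothelium (-2.28) and cell death (-2.45), again above the shift. Cell death was also reversed, at -0.028, without treated ischemic pool 1; over the arrays left out it ran from -0.028 to 0.16.

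In the order ischemia without the drug, drug after ischemia, drug without ischemia and ischemia with the drug, a fit of only the 2 groups gave 0, 0, 0 and 4, with fewer arrays to estimate the spread. All 17 arrays gave 40, 0, 2 and 21, with 1 for the difference of the responses. Without the 2 arrays with unlike labels the counts were 11, 0, 0 and 3. Quantile normalization gave 13 for ischemia without the drug and 0 for the drug alone. A floor at the 40th percentile gave 0 for the drug after ischemia and 16 for ischemia with the drug. No filter gave 0 for the drug alone and 1 for the difference. A filter on all arrays gave 0 for the drug after ischemia. Array weights gave 60 (54 up, 6 down), 2 for the drug alone and 14 with the drug. A trended and robust prior gave 0 for the drug after ischemia and 0 for the drug alone. Groups from the descriptions gave 0 for both drug comparisons.

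The replicate block gave 35 for ischemia without the drug and 0 for the drug alone; 16 lists passed for ischemia without the drug, 2 for the drug after ischemia and 2 for the difference. It moved no other count by more than 1.5 times, but for ischemia with the drug it ended the call of Bag3 (adjusted p = 0.0634) while 12 passed. With the scale set block, treated ischemic pool 1 alone stands for its group in the comparisons of pools, so no counts of passing are given for them. The share lower with the drug was 75.0% in that fit. Groups from the descriptions gave 3 lists for the drug after ischemia, 0 for the difference and a share of 71.4%; without the 2 arrays these were 3, 3 and 100%. With an estimated correlation, and likewise with fry, 0 lists passed for the drug after ischemia, 7 for ischemia with the drug and 0 for the difference. The share was reversed at 36.9% for probe sets raised in the single brains. These were chosen for high values in treated brains, which by itself favours the treated pools, and no value under no drug effect was computed for them. For single brains against treated pools, quantile normalization gave 10, the 40th percentile floor 0 and the scale set block 8; against untreated pools, no filter gave 33.

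Leaving out 1 array at a time gave 1 to 19 probe sets for ischemia without the drug, 0 to 0 for the drug after ischemia, 0 to 2 for the drug without ischemia, 1 to 6 for ischemia with the drug and 0 to 0 for the difference. Low counts came without control pools 1 (9) and 2 (7), ischemic pools 1 (1), 2 (5) and 3 (1), drug control pools 2 (5) and 3 (1), and each treated ischemic pool (1). Lists ran 8 to 14, 0 to 4, 0 to 2, 13 to 15 and 0 to 3 in the same order. For the drug after ischemia they were 2, 4 and 0 without ischemic pools 1, 2 and 3, and 3 without treated pool 1 or 3. For the drug alone they were 1 and 2 without control pools 1 and 3. For the difference they were 3 without control pool 1, ischemic pool 2 or treated pool 1, 2 without drug control pool 1 and 0 without control pool 3. The share ran from 77.8% to 100%, but 100% came over 1 probe set without ischemic pool 1 or 3, 5 without ischemic pool 2 and 7 without control pool 2. The spread ratio ran from 1.09 to 1.56, and single brains gave 4 to 41 against untreated pools (41 and 20 without ischemic pools 1 and 2, 4 without brain 13). Against treated pools they gave 4 to 98 (98 and 8 without treated pools 3 and 1, 9 without brain 11 or 12).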

Other observations

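No tests were added for this part, and only the values of Gfpt2 per pool were chosen after its result was seen; the other genes are those with the smallest p in gene lists fixed beforehand. Hemoglobin transcripts were higher in ischemic than in control pools: Hbb-b2 had a log2 difference of 2.50 (SE 0.60) and Hba-a1 of 1.43 (SE 0.43), both rising adjusted over the list alone (adjusted p = 0.0105 and 0.0211) and not over all probe sets (0.338 and 0.65). With the drug Hbb-b2 had 1.97 (SE 0.60; 0.0459 over the list alone) and Hba-a1 1.06 (SE 0.43; 0.0934). The erythroid anion exchanger Slc4a1 had -0.37 (SE 0.38) without and -0.82 (SE 0.38) with the drug.

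Of the genes that respond to glucocorticoids or the time of day, the phosphatase Dusp1 had a log2 difference of 1.14 (SE 0.20), the clock gene Cry1 of 0.58 (SE 0.17) and the glucocorticoid-induced Fkbp5 of -0.82 (SE 0.18) after ischemia without the drug. These 3 of 23 passed adjusted over the list alone, at 0.00395, 0.0429 and 0.0129; none passed over all probe sets. With the drug the values were 0.81, 0.48 and -0.60, and Dusp1 passed over the list alone (0.0491). Xanthine dehydrogenase Xdh, a source of superoxide, had -0.87 (SE 0.24; 0.0328 over the list alone) without and -0.43 (SE 0.24; 0.781) with the drug. The neurotrophin Bdnf had 0.81 (SE 0.30) and 0.87 (SE 0.30), with 0.326 and 0.328 over the list alone.

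Gfpt2 stood at 10.69, 10.90 and 10.52 log2 in the 3 drug control pools and at 8.54, 8.68 and 8.56 in the control pools. The ischemic pools had 10.10, 10.33 and 10.37, and the treated ischemic pools 10.58, 10.36 and 9.70. In the 5 single treated brains it ran from 9.28 to 9.69.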
